A study of Mus musculus with 25 samples.

How the data were processed

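The material was small extracellular vesicles (sEVs, membrane-bound particles that cells release) from the livers of wild-type C57BL/6J mice aged 1 week, 6 weeks, 6 months, 12 months or 14 months. Each age had 5 mice and 1 library per mouse, 25 libraries in all. Per the labels, tissue was opened with a tumour dissociation kit, vesicles were collected by ultracentrifugation, RNA was extracted with a serum and plasma miRNA kit, and QIAseq miRNA libraries were sequenced as paired-end reads on an Illumina NovaSeq. Per the labels, both sexes were equally represented, without the sex of each mouse. The label field for batch repeats the age, so any handling that differed between ages cannot be told apart from age. No paired analysis was possible because the mouse numbers are unique to each age.

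The authors deposited one table of raw counts, with 1493 entries and 25 columns of values. Of these entries, 1095 carry the name of a mouse mature miRNA and 398 are called unconservative with a pair of numbers; the latter hold 0.0836% of all counts and are not explained in the labels. The authors named Bowtie, edgeR and the mouse build mm10, without versions. Whether the counts are reads or unique molecular identifiers, which miRNA annotation was used and how many mismatches were allowed is not stated, so counting intervals and floors cover counting error only. The values are whole numbers. Among 50 pairs of libraries of 1 age none was identical, and the smallest chi-squared per degree of freedom was 12.1. In 21 pairs, covering 39 entries, the counts of 2 miRNAs were within 0.3 log2 units of each other in every library at a mean count of at least 20. Each such pair is thus not 2 independent results, and miR-29a-3p and miR-29c-3p form such a pair. So do miR-27a-3p and miR-27b-3p, miR-101a-3p and miR-101b-3p, and miR-19a-3p and miR-19b-3p. Counts of list members below include both entries of a pair.

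Library totals ran from 641579 to 6888928 counts. A miRNA with no count in a library of this depth lies below a floor of 3 counts, which equals 4.90 counts per 1000000 (CPM) in the shallowest library and 0.283 CPM in the deepest. CPM values in the text, these floors included, were scaled with TMM factors, so they can be higher or lower than the share of raw counts; shares are given as percentages of raw counts. Folds against an age without a count are lower bounds against 3 counts over the whole age group; folds against 1 to 3 counts carry a 95% exact binomial (Clopper-Pearson) interval.

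Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Entries passing filterByExpr were kept, 391 tested and 1102 not tested; of the 391, 339 have a miRNA name and 52 are unconservative. One quasi-likelihood model (TMM factors, robust spread) of all 25 libraries gave an F test over the 5 ages and 5 pairwise contrasts: 6 weeks against 1 week, 6 months against 6 weeks, 12 months against 6 months, 14 months against 12 months, and 14 months against 6 weeks. The Benjamini-Hochberg threshold was an adjusted p of 0.05 in each contrast. The biological coefficient of variation was 37.6%. The model was tested on simulated data with the spread and depth of these libraries. For 6 weeks against 1 week it recovered 61.5% of 2-fold and 95.8% of 4-fold changes, with 4.46% unchanged miRNAs among the calls. For 14 months against 6 weeks the figures were 55.1%, 92.1% and 2.59%. The simulated changes were balanced between higher and lower, on the mean profile of the younger age, without a trend with depth. These figures thus do not cover errors from the scaling or from such a trend. The simulated changes were also dense: for 14 months against 6 weeks, 78 of 2-fold and 76 of 4-fold among 349 tested entries. The real comparison had 15 calls of 391, so its recovery can be lower than these figures.

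These comparisons, 14 miRNA lists and the rule for naming miRNAs were fixed before the data were examined. The lists covered hepatocyte, erythroid, immune, endothelial, stellate and smooth muscle, biliary and other epithelium, and other tissues as markers of the cells a liver preparation can hold. The remaining lists were the Dlk1-Dio3 cluster, the H19 and Igf2 loci, the let-7 family, the miR-17-92 and paralog clusters, the X-linked Fmr1-Slitrk2 cluster, lipid and cholesterol metabolism, and ageing and senescence. Lists with at least 3 tested members were tested with camera (limma, preset correlation of 0.01), adjusted over 55 tests, and again with an estimated correlation and with fry. Named were the 8 largest rises and the 8 largest falls (4 and 4 for consecutive adult ages) past the threshold at a mean of at least 50 CPM, up to 4 members of each list, and the 5 most abundant miRNAs. Remaining calls were added to the named miRNAs after their values were seen.

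Shares of counts, library totals and numbers of detected miRNAs were compared with exact two-sided permutation tests of 5 against 5 libraries (scipy 1.17.1), adjusted over 15 tests in each family; the smallest p these can give is 0.00794. Similarity of libraries was tested with PERMANOVA (vegan 2.7.1, 9999 permutations) on log2 CPM with a prior count of 2. Precursor positions on mm10 came from the GENCODE M21 annotation; 195 of 199 named or listed miRNAs matched a precursor gene by name.

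Alternative settings fixed with the comparisons were DESeq2 size factors, library totals alone, scaling without miR-122-5p, no filter, a filter of 10 CPM in 5 libraries, DESeq2 1.42.0, limma-voom with quality weights, a spread without robust fitting, the compared ages alone, and leaving out each library. After the data were seen, further alternatives were added: counts thinned to the smallest total, log2 library total as a covariate, 1 entry kept of each near-identical set, named miRNAs alone, log2 library total entered before age for the adult libraries, and fits without the 1-week libraries of mice 4 and 27 or the 6-week libraries of mice 6 and 7. Sequences and raw reads were not used here.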

Results

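Small RNA was counted in 25 libraries of liver sEVs from mice of 5 ages, 5 mice at each age. For every mean below n = 5 per age holds, with the SD after it, and log2 fold changes carry their SE. This SE was taken as the size of the log2 fold change over the square root of its quasi-likelihood F statistic. It is thus approximate, above all where an age has few counts. Library totals averaged 3348808 ± 1990633 counts at 1 week, 1046872 ± 426813 at 6 weeks, 1413686 ± 603587 at 6 months, 2179828 ± 1139953 at 12 months and 2457390 ± 993097 at 14 months. The hepatocyte miRNA miR-122-5p, the most abundant miRNA of liver, held 58.3% ± 3.22 of counts over the 25 libraries. It was followed by miR-148a-3p, miR-126a-3p, miR-192-5p and miR-26b-5p. The miR-122-5p share was 61.8% ± 4.29 at 1 week, 58.4% ± 2.75 at 6 weeks, 56.8% ± 1.73 at 6 months, 56.0% ± 1.31 at 12 months and 58.4% ± 2.49 at 14 months. None of its 5 differences between ages passed the exact permutation test, with the smallest adjusted p at 0.536. The precursor gene Mir122 lies on chromosome 18 of mm10 from 65248861 to 65248926, in an exon of a long noncoding RNA.

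Whether the vesicle miRNAs differ with age at all was asked across the 5 groups. The 1-week libraries stood apart from all adult libraries, between -42.7 and -35.4 on the first principal component, against 3.56 to 14.6 for the 20 adult libraries. Age accounted for a fraction of 0.765 of the variation between libraries (permutation test on distances, p = 0.0001, the smallest it can give). Among the 20 adult libraries the fraction was 0.264 (permutation p = 0.0056), but with log2 library total entered first it was 0.158 and did not pass (permutation p = 0.0958). Their first principal component, computed without the 1-week libraries, followed log2 library total closely (Pearson r = 0.898), so age and depth were not separated among adults. In the edgeR test over the 5 ages, 295 of 391 tested entries (75.4%) changed; of the 391, 339 are named miRNAs and 52 are unconservative entries.

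**Figure D1:**
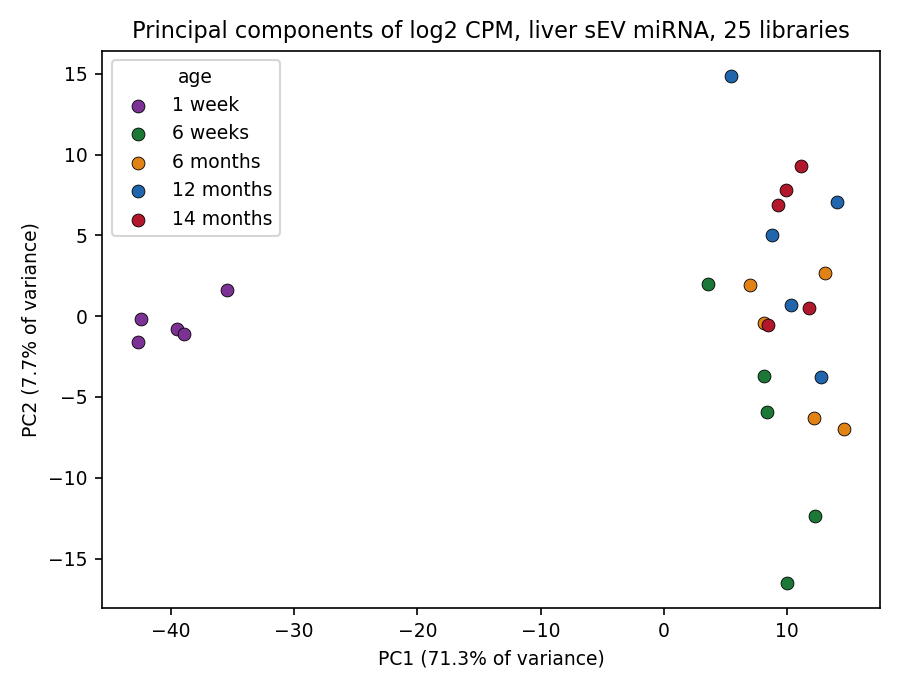
First and second principal component of log2 CPM, each point 1 library coloured by age, with the percentage of variance on each axis. The 5 libraries of 1 week lie between -42.7 and -35.4 on the first component and the 20 adult libraries between 3.56 and 14.6.

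The comparison of 6 weeks with 1 week asked how vesicle miRNAs of young adult liver differ from those of the first postnatal week. Several members of the miR-29 family, which represses collagens and other matrix genes, were far higher at 6 weeks: miR-29b-3p rose from 75.6 ± 30.2 to 1119 ± 297 CPM, a log2 fold change of 3.88 ± 0.27 (adjusted p = 8.67e-12). The 2 miRNAs with nearly equal counts, miR-29a-3p and miR-29c-3p, rose by 3.58 ± 0.33 each, and miR-29c-5p rose by 4.76 ± 0.29. Lower at 6 weeks were miRNAs of the imprinted Dlk1-Dio3 and Igf2 loci and of skeletal muscle. For example, miR-379-5p fell from 9433 ± 7356 to 78.4 ± 31.8 CPM and miR-483-5p from 1456 ± 437 to 5.40 ± 8.17 CPM, or 1.84 CPM without mouse 10. In all of these the 5 libraries of 6 weeks lay beyond the 5 of 1 week. Of the other miR-29 members, miR-29b-2-5p rose by 2.26 ± 0.80 (edgeR adjusted p = 0.0133) but was not called with library totals alone (1.64, adjusted p = 0.0671). The miR-29 family was not among the lists and was not tested as a set.

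Among hepatocyte miRNAs, 10 of 12 tested members rose, none fell and 2 did not pass. The miR-192 and miR-194 pair, transcribed together and abundant in liver and gut, led the list: miR-194-5p rose by 2.21 ± 0.12 (adjusted p = 2.29e-13), miR-192-5p by 2.27 ± 0.21 and miR-192-3p by 3.76 ± 0.31. The minor arm miR-122-3p rose by 2.11 ± 0.24. For miR-122-5p the log2 fold change was 0.56 ± 0.12 (adjusted p = 0.000196), but -0.084 (adjusted p = 0.165) with library totals alone and 0.099 (adjusted p = 0.399) with DESeq2 size factors. Likewise miR-148a-3p, higher by 0.67 ± 0.17, was at 0.014 (adjusted p = 0.916) with library totals alone. Its call was lost in 4 of 25 alternatives, that one included. The list was called by camera (adjusted p = 0.0033), with an adjusted p = 0.350 with an estimated correlation. Of the other most abundant miRNAs, miR-26b-5p rose by 0.85 ± 0.18, with an adjusted p of 0.147 under library totals alone.

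In the let-7 family, whose members accumulate as tissues differentiate, 11 of 16 rose, 3 fell and 2 did not pass. The largest rise was that of let-7g-5p, from 1336 ± 363 to 11892 ± 1840 CPM (3.15 ± 0.19), ahead of let-7f-5p (1.54 ± 0.15), let-7a-5p (1.46 ± 0.14) and let-7d-5p (1.34 ± 0.15). The family was called by camera (adjusted p = 0.0168), but not with library totals alone (adjusted p = 0.0601), and had an adjusted p = 0.633 with an estimated correlation. Of 20 miRNAs tied to lipid and cholesterol metabolism 10 rose and 5 fell, and with library totals alone 6 rose and 6 fell. The risers included miR-27b-3p (2.02 ± 0.15), miR-27a-3p (1.93 ± 0.15), miR-30c-5p (1.93 ± 0.16) and miR-378a-3p (2.30 ± 0.20), the last carried in an intron of Ppargc1b. Of these, miR-27a-3p and miR-27b-3p have nearly equal counts and are not separate results. Of 14 ageing and senescence miRNAs 7 rose and 3 fell, and with library totals alone 5 rose and 6 fell; miR-21a-5p, which is linked to growth and fibrosis, rose by 2.26 ± 0.28. Neither list was called by camera, with adjusted p of 0.134 and 0.265.

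Of 96 entries of the Dlk1-Dio3 cluster, an imprinted locus active in the embryo and fetus, 56 were tested and all 56 fell. The 56 come from 38 precursors on chromosome 12 between 109571990 and 109743496. An entry that passed the filter through the 1-week libraries alone could only be lower at 6 weeks, so this count is partly set by the filter. The median log2 fold change was -5.34, or -4.97 with 8 members that had no count at 6 weeks set at their bound. Summed over the cluster the level was 20093 ± 7951 CPM at 1 week, 378 ± 171 at 6 weeks and 366 ± 162 at 14 months. Examples are miR-382-5p (-6.64 ± 0.47, adjusted p = 1.03e-11), miR-134-5p (-7.24 ± 0.63), miR-323-3p (-6.34 ± 0.53, or -7.02 without mouse 10), miR-494-3p (-6.19 ± 0.53), miR-379-5p (-6.89 ± 0.63) and miR-673-5p (-6.74 ± 0.61). With no count at 6 weeks, miR-329-3p was at least 112-fold lower, or 67.9-fold without mouse 27. Camera called the list (adjusted p = 5.2e-24), and the call held with an estimated correlation (adjusted p = 0.0495). All 56 members were lower also under the 3 other scalings.

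**Figure D2:**
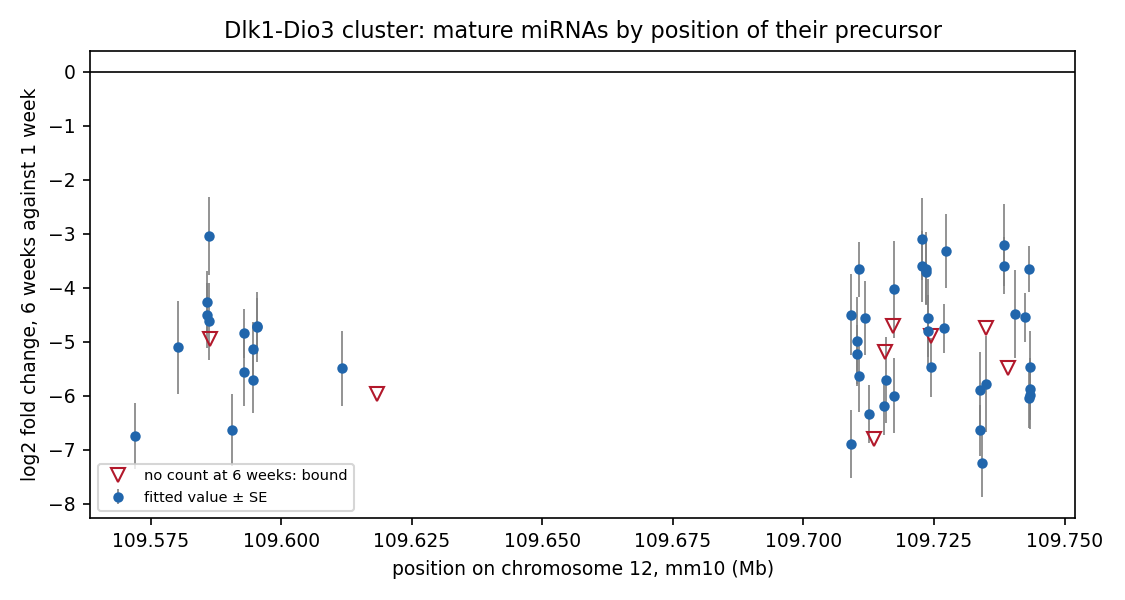
Log2 fold change (6 weeks against 1 week, SE as bars) of the mature miRNAs of the Dlk1-Dio3 cluster against the start of their precursor on chromosome 12, in Mb of mm10. Circles are fitted values and hollow triangles are bounds for members with no count at 6 weeks; all 56 lie below 0, the highest at -3.04.

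The H19 and Igf2 loci, imprinted genes of fetal growth that are shut down in liver after birth, had 3 tested miRNAs and all 3 fell (camera adjusted p = 0.139). Mir483 lies in an intron of Igf2 on chromosome 7 (142654924 to 142654996) and Mir675 in an exon of H19 (142577064 to 142577147). The fitted fall of miR-483-5p was -7.77 ± 0.93 (adjusted p = 8.65e-08), and -9.49 without mouse 10. With 1 count at 6 weeks, miR-483-3p had a ratio of 301 between 1 week and 6 weeks (95% interval 54.0 to 11905); that count was from mouse 10, and without it the fall was at least 67.8-fold. With 3 counts, miR-675-3p had a ratio of 100.1 (34.2 to 486), which was 203 (36.3 to 8015) without mouse 10 and 58.1 (19.8 to 282) without mouse 27. From the Gnas region of chromosome 2, also imprinted, miR-298-5p had 1 count at 6 weeks and a ratio of 624 (112 to 24646), or at least 179 without mouse 6, which held that count. The X-linked Fmr1-Slitrk2 cluster, known from testis, had 2 tested members: miR-547-3p rose by 1.61 ± 0.63 (adjusted p = 0.0241) and miR-741-3p, without a count at 1 week, was at least 11.7-fold higher from 7 counts. That bound was 2.14-fold without mouse 9, and it was lower also without the deep library of mouse 27. With library totals alone miR-547-3p lost its call (adjusted p = 0.159). It also lost it without mouse 6, 9 or 10 (adjusted p from 0.0544 to 0.0675) and was at 2.64 without mouse 27. The call of miR-741-3p was lost in 2 alternatives, without mouse 9 (adjusted p = 0.102) and under another setting (adjusted p = 0.265).

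Several but not all markers of blood, and the tested markers of epithelium and of skeletal and heart muscle, were higher in the 1-week libraries. Of 5 erythroid entries 4 fell to 6 weeks, with miR-486a-5p at -2.28 ± 0.31, miR-144-3p at -1.91 ± 0.36 and miR-144-5p at -1.53 ± 0.45. Among the 4, miR-486b-5p repeats the counts of miR-486a-5p and is not a separate result. The remaining member, miR-451a, was at -0.26 and did not pass. The erythroid share, which counts miR-486a-5p and miR-486b-5p both, went from 0.117% ± 0.0323 to 0.0346% ± 0.0148 (exact permutation p = 0.00794, adjusted p = 0.119). This p is the smallest the test can give, so as the only 1 of 15 share tests at that value it could not pass. Each 1-week library, at 0.0642% or more, lay above every 6-week library, at 0.0537% or less. Of 8 immune miRNAs 5 fell, among them the myeloid miR-223-3p (-2.30 ± 0.22) and miR-223-5p (-2.61 ± 0.60), miR-155-5p (-2.16 ± 0.51) and miR-142a-5p (-0.91 ± 0.23). Without both mouse 6 and mouse 7 miR-144-5p (-1.11, adjusted p = 0.0531) and miR-142a-5p (-0.60, adjusted p = 0.0710) lost their calls, which all other settings kept. All 6 epithelial miRNAs fell, including miR-429-3p (-2.20 ± 0.26), miR-200b-3p (-1.43 ± 0.23), miR-200c-3p (-1.39 ± 0.26) and miR-200a-3p (-1.12 ± 0.17). The muscle miRNAs miR-206-3p and miR-1a-3p fell by 8.13 ± 0.80 and 4.12 ± 0.69 on the log2 scale, and miR-206-3p went from 389 ± 372 to 1.20 ± 0.785 CPM. Without mouse 27 they were at -7.42 and -3.05. The erythroid, immune and epithelial lists were not called by camera (adjusted p of 0.157, 0.268 and 0.0720), although fry called each of the 11 lists.

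Of 9 stellate and smooth muscle miRNAs 3 rose: miR-145a-5p (1.03 ± 0.18), miR-145a-3p (1.21 ± 0.24) and miR-143-3p (0.69 ± 0.14). With library totals alone miR-145a-5p (adjusted p = 0.0671) and miR-143-3p (adjusted p = 0.895) lost their calls, the latter also with DESeq2 size factors (adjusted p = 0.187), with DESeq2 itself and with no filter. With library totals alone 1 of the 9 was higher and 6 lower, so the direction of this list rests on the scaling (camera adjusted p = 0.666). The endothelial miR-126a-3p, hosted by Egfl7, rose by 0.90 ± 0.16 and lost its call with library totals alone (adjusted p = 0.140), under which 1 of 2 endothelial members was lower. In the miR-17-92 and paralog clusters, which drive proliferation, 8 of 14 fell and 2 rose; with library totals alone 9 fell and none rose (camera adjusted p = 0.451). Lower were miR-20b-5p (-2.83 ± 0.60), miR-106b-3p (-2.08 ± 0.46) and miR-18a-5p (-1.93 ± 0.30), while miR-19a-3p was higher by 0.99 ± 0.22. The miR-19a-3p call was lost in 3 of 25 alternatives, among them library totals alone (adjusted p = 0.260).

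**Figure D3:**
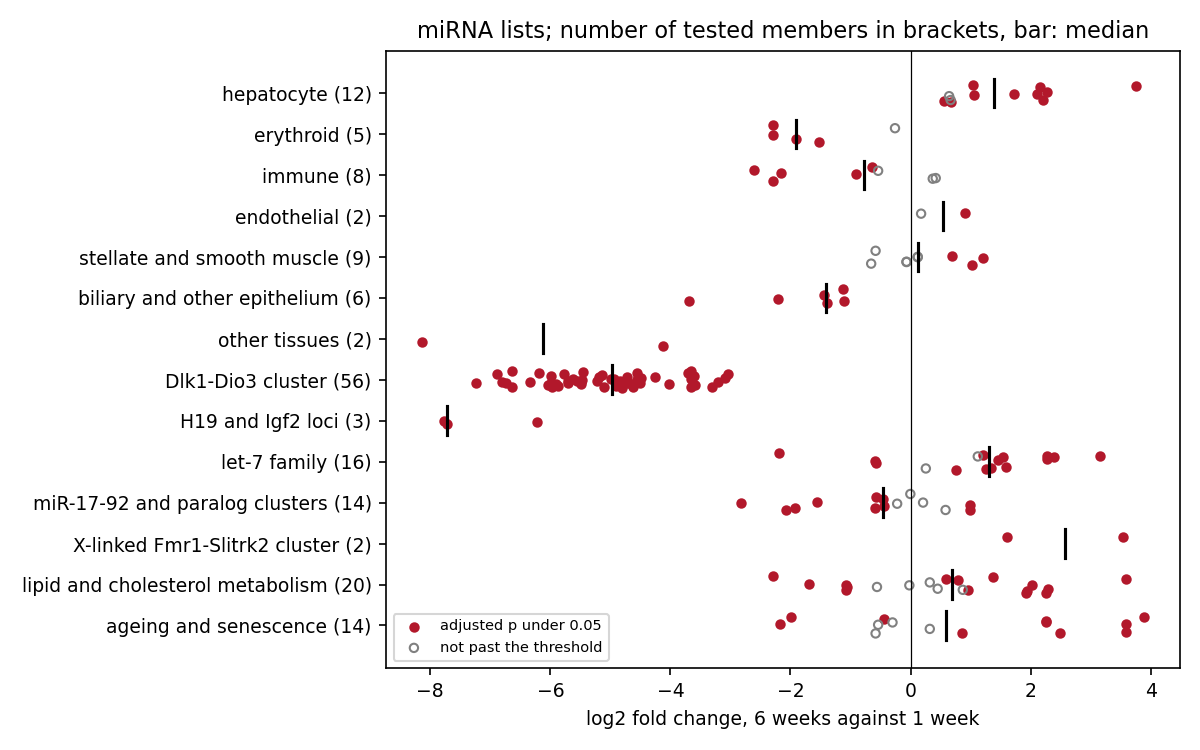
Log2 fold change (6 weeks against 1 week) of each tested member of the 14 lists, filled where the adjusted p is under 0.05, with the median as a bar and members without a count in 1 group at their bound. All 56 Dlk1-Dio3 members lie below 0 and 10 of 12 hepatocyte members are higher.

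In edgeR 281 of 391 tested entries changed from 1 week to 6 weeks, 137 higher and 144 lower, and 244 by at least 2-fold. Of the tested members another list held 6 in the ageing, 4 in the lipid, 2 in the immune, 1 in the stellate and 1 in the miR-17-92 list. In each list the counts adjusted over the list alone equalled those over all tested miRNAs. DESeq2 size factors moved the median of all miRNAs by -0.46 and gave 107 higher and 165 lower; library totals alone moved it by -0.66 and gave 88 higher and 178 lower. Of the calls, 23 are unconservative entries, such as unconservative_10_2277460 (4.85 ± 1.06) and unconservative_5_1281946 (3.14 ± 0.45); the first lost its call with library total as a covariate (1.12, adjusted p = 0.336) and was at 3.71 without mouse 6.

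The comparison of 14 months with 6 weeks asked what differs between young adult mice and the oldest age. On its own it does not separate changes before 6 months from later ones. The smallest adjusted p of a rise was that of miR-29b-3p, which went from 1119 ± 297 to 3953 ± 1149 CPM, a log2 fold change of 1.82 ± 0.25 (adjusted p = 2.09e-05), with 5 of 5 old libraries above every young one. Higher by 1.44 ± 0.30 each (adjusted p = 0.00443) were miR-29a-3p and miR-29c-3p, with 4 of 5 old libraries above every young one; with log2 library total in the model they were at 0.65 ± 0.23 and not called (adjusted p = 0.219). The tested 5p arms of the family did not pass: miR-29a-5p was at 0.39 ± 0.45 (adjusted p = 0.617), miR-29c-5p at 0.035 ± 0.24 (adjusted p = 0.919) and miR-29b-2-5p at 1.06 ± 0.71 (adjusted p = 0.383). Also higher were miR-221-3p (0.61 ± 0.16) and miR-222-3p (0.86 ± 0.24), neighbours on the X chromosome that repress the cell cycle inhibitor p27. The X-linked miR-741-3p rose from 1.26 ± 2.31 to 27.2 ± 12.3 CPM (4.27 ± 0.74, adjusted p = 0.00121; 6.50 without mouse 9). The largest fall was that of miR-383-5p, hosted by an intron of Sgcz, from 38.1 ± 26.1 to 0.607 ± 0.651 CPM (-5.83 ± 0.66, adjusted p = 1.17e-06). Being below 50 CPM at both ages, miR-383-5p was outside the naming rule and was chosen after its values were seen.

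In all, 15 of 391 tested entries changed in edgeR, 13 higher and 2 lower, and 9 by at least 2-fold. Beyond those named, miR-137-3p (1.33 ± 0.35), miR-182-5p (0.77 ± 0.22), miR-101c (0.70 ± 0.20) and miR-194-5p (0.45 ± 0.12) were higher. Outside the naming rule like miR-383-5p, and also chosen after their values were seen, were 3 rises and 1 fall. Here miR-3065-5p (3.56 ± 0.75), miR-184-3p (2.93 ± 0.63, or 3.70 without mouse 10) and miR-152-3p (0.60 ± 0.16) rose and unconservative_17_3545063 fell by 2.37 ± 0.64. Mir29b-1 lies on chromosome 6 (31063023 to 31063093) and Mir29b-2 on chromosome 1 (195037040 to 195037120), each beside its partner Mir29a or Mir29c. Mir383 lies on chromosome 8 (38252133 to 38252202) and Mir741 on chromosome X (66796805 to 66796875).

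Of 14 ageing and senescence miRNAs miR-29a-3p, miR-29b-3p and miR-29c-3p rose and 11 did not pass, miR-29b-2-5p among these; miR-34a-5p, which p53 induces, was at 0.73 ± 0.35 (adjusted p = 0.202) and miR-146a-5p at 0.76 ± 0.34 (adjusted p = 0.199). Camera called this list at a median of 0.64, or 0.41 without mouse 24 (adjusted p = 0.00481; adjusted p = 0.456 with an estimated correlation). In the lipid and cholesterol list miR-29a-3p and miR-182-5p rose among 20, or 3 adjusted over the list alone (camera adjusted p = 0.0753). None of 16 let-7 members passed, although camera called the family at a median of 0.27 (adjusted p = 0.0189; adjusted p = 0.633 with an estimated correlation). None of 9 stellate members passed over all miRNAs and 2 did adjusted over the list alone. That list was called by camera at a median of 0.37 (adjusted p = 0.0378; adjusted p = 0.578 with an estimated correlation). With library totals alone the medians of let-7 and stellate members were 0.0027 and 0.0996, and both calls ended (adjusted p of 0.203 and 0.219). The let-7 call ended also without mouse 9, 24 or 25 (adjusted p from 0.0563 to 0.0590) and the stellate call without mouse 7, 8, 21, 24 or 25 (0.0553 to 0.0666). Fry called the ageing (fry adjusted p = 0.0288), lipid (0.00614) and stellate (0.0164) lists, but not the let-7 family (0.0616).

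In the hepatocyte list miR-194-5p alone passed, 1 of 12 (camera adjusted p = 0.0821, fry adjusted p = 0.0411). Of the 5 erythroid, 8 immune, 2 endothelial, 6 epithelial, 2 muscle, 56 Dlk1-Dio3, 3 H19 and Igf2 and 14 miR-17-92 cluster members none passed, and no camera test of the 6 lists among these large enough to test was called. Members of these lists were at these values: miR-451a (-0.50 ± 0.35), miR-146a-5p (0.76 ± 0.34), miR-142a-3p (0.11 ± 0.21), miR-126a-3p (-0.13 ± 0.16), miR-126a-5p (0.20 ± 0.20), miR-200a-3p (0.33 ± 0.17), miR-379-5p (-0.11 ± 0.51) and miR-93-5p (0.10 ± 0.15). Of the 2 X-linked cluster members miR-741-3p alone passed. For miR-122-5p the value was 0.27 ± 0.12 (adjusted p = 0.199).

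**Figure D4:**
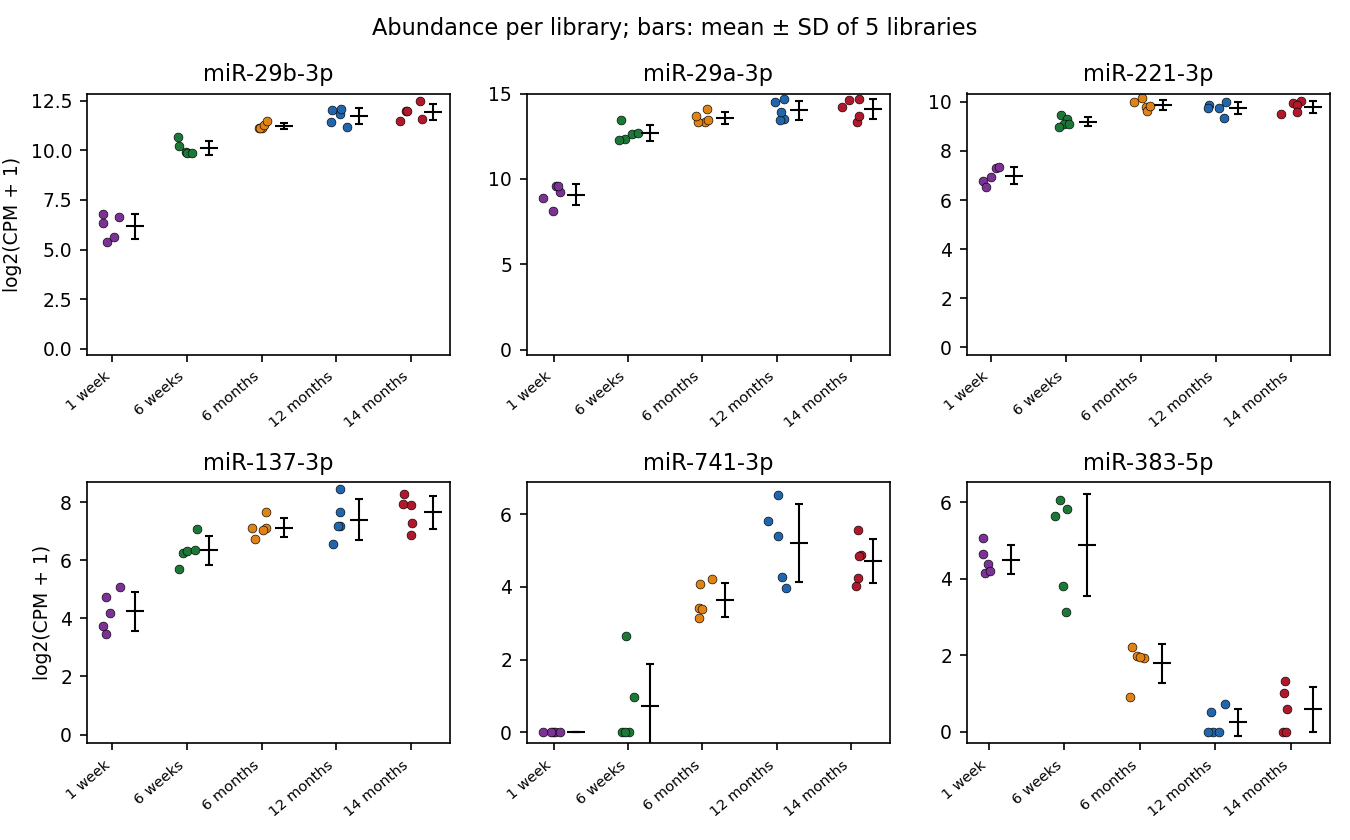
Abundance as log2 of CPM plus 1 in each of 25 libraries for 6 miRNAs, by age, with the mean and SD of 5 libraries as bars. From 6 weeks to 14 months miR-29b-3p goes from 1119 to 3953 CPM and miR-383-5p, chosen after its values were seen, from 38.1 to 0.607 CPM.

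Mean library totals were higher at 14 months, a difference that did not pass after adjustment (exact permutation p = 0.0238, adjusted p = 0.0714). With log2 library total as a covariate 7 miRNAs were called, miR-29b-3p among them (1.20 ± 0.20, adjusted p = 0.000713) but neither miR-29a-3p nor miR-29c-3p. Library totals alone moved the median by -0.27 and gave 6 higher and 5 lower, limma-voom called 52, and leaving out mouse 23, 24 or 25 left 8 calls each.

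Without any 1 library of the 10, 7 of the 15 calls held: miR-29b-3p, miR-29a-3p, miR-29c-3p, miR-741-3p, miR-3065-5p, miR-184-3p and miR-383-5p. The other 8 were each lost without at least 1 library. Those were, for miR-221-3p, mouse 8, 9, 10, 21 or 22 (adjusted p from 0.0534 to 0.0752), and for miR-222-3p mouse 6, 7, 8, 10, 21, 23, 24 or 25 (0.0517 to 0.104). For miR-137-3p they were mouse 6, 7, 8, 23, 24 or 25 (0.0524 to 0.105), for miR-194-5p mouse 6, 7, 21, 23, 24 or 25 (0.0547 to 0.155), and for miR-182-5p any but mouse 21 (0.0524 to 0.106). The call of miR-101c was lost without any but mouse 22 (0.0529 to 0.215). Those of miR-152-3p (0.0524 to 0.155) and unconservative_17_3545063 (0.0907 to 0.118) were lost without mouse 6, 7, 23, 24 or 25.

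From 6 weeks to 6 months, young to mature adult, 7 of 391 tested entries changed in edgeR, 4 higher and 3 lower. Past the abundance limit of 50 CPM were miR-29b-3p, higher by 1.11 ± 0.25 at 2413 against 1119 CPM, all 5 older libraries above the younger ones (adjusted p = 0.0162), and miR-221-3p, higher by 0.70 ± 0.17 (adjusted p = 0.0255). The other calls, chosen after their values were seen, were miR-741-3p (3.09 ± 0.78; 5.31 without mouse 9) and miR-184-3p (2.45 ± 0.64; 3.20 without mouse 10), both higher, and miR-383-5p (-3.77 ± 0.57), miR-409-5p of the Dlk1-Dio3 cluster (-3.24 ± 0.65, or -4.75 without mouse 13) and miR-669c-5p (-1.63 ± 0.43), all lower. Camera called the let-7 family at a median of 0.20 with no member passing (adjusted p = 0.0374; adjusted p = 0.662 with an estimated correlation), and no other list. Adjusted over the list alone, 3 ageing members and 1 hepatocyte member rose and 1 ageing member fell. Library totals alone moved the median by -0.12 and left 3 calls; leaving out single libraries gave 1 to 9 calls: 1 without mouse 14, 2 without mouse 15, 3 without mouse 8 or 11, and 4 without mouse 6, 7, 9 or 12. Only miR-383-5p held without any 1 library of the 10; miR-29b-3p was lost without mouse 14 or 15 (adjusted p of 0.0610 and 0.0556), miR-221-3p without mouse 8, 9, 11, 14 or 15 (0.0556 to 0.0990) and miR-409-5p without mouse 14 (0.0539). The calls of miR-741-3p (any but mouse 9, up to 0.143), miR-184-3p (any but mouse 10, up to 0.158) and miR-669c-5p (any but mouse 10 or 13, up to 0.153) were the least steady. The let-7 call ended without 15 of the 25 libraries, mice 5, 6, 8, 9, 11, 14 to 18 and 21 to 25 (adjusted p from 0.0524 to 0.234). Fry did not call the family (fry adjusted p = 0.267).

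From 6 months to 12 months no miRNA changed in edgeR; 28 had an unadjusted p under 0.05, the smallest adjusted p was 0.358, and DESeq2 and limma-voom called none. Camera called the stellate and smooth muscle list at a median of 0.40 (adjusted p = 1.38e-05; adjusted p = 0.121 with an estimated correlation). The ageing list at 0.39 (adjusted p = 0.00481) and the immune list at 0.33 (adjusted p = 0.0168) were called too, each with an adjusted p = 0.456 with an estimated correlation. Fry called the stellate list (fry adjusted p = 0.00888) but neither the immune (0.267) nor the ageing list (0.273). The immune call by camera ended without mouse 13 or 17 (adjusted p of 0.109 and 0.173). Without mouse 14 or 18 the medians were 0.67 and 0.59 for the immune and 0.68 and 0.63 for the ageing list. Adjusted over the list alone 2 immune members, 1 ageing member and 1 of the X-linked cluster rose. From 12 months to 14 months again no miRNA changed in edgeR, 8 had an unadjusted p under 0.05, and DESeq2 and limma-voom called none. The lipid and cholesterol list was called at a median of 0.19 (adjusted p = 0.0378; adjusted p = 0.321 with an estimated correlation), and miR-122-5p was at 0.18 ± 0.12. That list call ended without mouse 5, 14, 16, 17, 18, 23, 24 or 25 (adjusted p from 0.0506 to 0.147), and fry did not call the list (fry adjusted p = 0.0536).

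Depth itself differed between ages. At 6 weeks 617 ± 36.5 miRNAs had at least 1 count, against 795 ± 73.8 at 1 week, and 232 ± 25.1 against 470 ± 134 had at least 10 (exact permutation p = 0.00794, adjusted p = 0.0397 for both and for library totals). Thinned to 641579 counts each, the libraries held 196 ± 8.02 miRNAs of at least 10 counts at 6 weeks and 270 ± 9.40 at 1 week. The 10 most abundant miRNAs held 83.4% ± 1.40 of counts at 6 weeks and 81.1% ± 3.37 at 1 week, and with miR-122-5p left out 60.2% ± 1.35 and 50.7% ± 3.85; no difference in the former share passed, with the smallest adjusted p at 0.536.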

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

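All tests in this part, and their division into parts, were chosen or given their bounds only after the results were seen. A first division of the calls between 6 weeks and 14 months, into miR-29 members and the rest, had been looked at before the rule for judging a scaling was set. A second, into 4 parts, was looked at before unconservative_17_3545063 was set apart from the other calls below 50 CPM to give the 5 parts used here.

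In 17 of 218 groups of 5 libraries a single library lay far from the other 4, where chance gives about 1 in 20, or 10.9. By depth, mouse 27 at 1 week had 6888928 counts (the others 2095925 to 2621883) and 709 miRNAs of at least 10 counts (399 to 417), and mouse 14 at 6 months 2485335 counts (1052751 to 1258885). Mouse 27 also had the highest muscle miR-1a-3p of its age, 119 CPM (6.38 to 31.6). Among 6-week libraries, mouse 10 had 11383 CPM of miR-29a-3p (5048 to 6609) and 11417 of miR-29c-3p (5079 to 6623), and more of 3 imprinted miRNAs: 19.6 CPM of miR-483-5p (0 to 4.84), 0.595 of miR-483-3p (others at 0) and 9.52 of miR-494-3p (2.79 to 4.43). Mouse 6 was lowest for miR-144-5p at 1.40 CPM (11.4 to 15.1) and alone had miR-298-5p, at 1.40 CPM, and mouse 9 had 5.31 CPM of miR-741-3p (0 to 0.969). At 6 months mouse 13 had 2.63 CPM of miR-409-5p (0 to 0.521). At 14 months mouse 25 had 17.9 CPM of miR-3065-5p (12.4 to 13.8), 3.04 of miR-483-5p (0 to 0.727) and 0.338 of miR-483-3p (others at 0), and mouse 21 had 7.47 CPM of unconservative_17_3545063 (2.57 to 3.72). The flagged values of miR-298-5p and miR-483-3p lay below the floor of 3 counts in their libraries. With the other 4 libraries at 0 any count gives such a flag. Mice 10 and 25 had the deepest libraries of their ages. No explanation was tested for these single libraries.

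Libraries were regrouped at random in 100 splits for each comparison, the real one included. For the 5 ages 1 split gave as many changed entries as the real one (295; highest other 148), for 6 weeks against 1 week 1 (281; highest other 119) and for 14 months against 6 weeks 1 (15; highest other 6). For 6 months against 6 weeks 2 did (7; highest other 8). Chance alone can be excluded for the first 3 of these counts at a share under 0.05 of the splits. For 6 months against 6 weeks the share was also under 0.05, but another split gave more changed entries than the real one. Chance is thus less firmly excluded there. The splits were not repeated without single libraries, where the 7 became 1 without mouse 14, 2 without mouse 15, 3 without mouse 8 or 11 and 4 without mouse 6, 7, 9 or 12, and the 15 became 8 without mouse 23, 24 or 25; so the exclusion holds for the full set of libraries only. For 12 months against 6 months and 14 months against 12 months, where edgeR called 0 miRNAs, all 100 splits gave as many (highest others 4 and 1); 28 and 8 miRNAs had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0.

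The miRNAs that changed between 6 weeks and 14 months were set against library depth and scaling, since libraries were deeper on average at 14 months. For miR-29b-3p, 1 of 1 call held with log2 library total in the model (1.82 ± 0.25 before, 1.20 ± 0.20 after) and 1 of 1 in all 3 other scalings, which argues against either as the whole cause. For miR-29a-3p and miR-29c-3p, 2 of 2 held in all scalings but 0 of 2 with library total in the model, where 1.44 ± 0.30 became 0.65 ± 0.23; the fold shrank, so a trend with depth cannot be told apart from age. Of the 4 named miRNAs called below 50 CPM at both ages, 4 held in all scalings and 4 with library total, at a median size of 3.91 before and 4.19 after, which argues against either as the whole cause. For unconservative_17_3545063, called in 1 of 1 case in all scalings but 0 of 1 with library total (-2.37 ± 0.64 before, -0.92 ± 0.68 after), a trend with library depth is a candidate explanation. Of the 7 others 0 held in all 3 scalings, and 1 with library total, where all 7 kept their sign at a median size of 0.57 (0.70 before) and a median SE of 0.25 (0.20 before). The folds of miR-137-3p (1.33 to 0.58), miR-152-3p (0.60 to 0.28) and miR-222-3p (0.86 to 0.55) shrank, those of miR-101c (0.70 to 0.62), miR-221-3p (0.61 to 0.57) and miR-194-5p (0.45 to 0.39) moved little while their SE grew, and that of miR-182-5p rose to 1.09; depth and scaling cannot be told apart from age for this part. Age remains an open explanation throughout, and so does handling that differed between ages.

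The fall of the Dlk1-Dio3 cluster from 1 week to 6 weeks was weighed in the same way. All 56 of 56 members were lower under each of the 3 other scalings, and after thinning to equal totals all 43 of the 43 members still tested were lower, which argues against scaling and against deeper 1-week libraries as the cause. The 8 tested miRNAs of other imprinted loci, in a list written after those counts were viewed and with miR-298-5p among them, had a median log2 fold change of -2.28. A list chosen in that way cannot test a wider fall of imprinted loci, so this stays open. A tissue other than liver at 1 week was not tested. By library the summed cluster was 13341, 15094, 23754, 15885 and 32390 CPM in mice 1, 3, 4, 5 and 27, and the muscle miR-206-3p 275, 148, 481, 50.4 and 990 CPM.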

How the results depend on the processing

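Tests chosen only after the data were seen were thinning in the counts of changed miRNAs, library total as a covariate, 1 entry of each near-identical set, named miRNAs alone, the similarity of the adult libraries with its alternatives, and fits without mice 4 and 27 or without mice 6 and 7. For comparisons and shares 102 values kept their side of the threshold or their size under other settings, 13 moved, 1 lost its call and 1 reversed; for named miRNAs 1553 did, 98 lost and 4 gained a call and 1 reversed; for lists 253 did, 22 lost and 11 gained a call. Named calls that held under each setting and without each library were 44 of 56 for 6 weeks against 1 week, 1 of 7 for 6 months against 6 weeks and 5 of 15 for 14 months against 6 weeks.

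The 5-age count stayed between 223 and 404 (286 to 318 without single libraries), that of 6 weeks against 1 week between 217 and 318 (at least 273), and the variation explained by age between 0.727 and 0.943 (0.738 to 0.778). Reversed were miR-122-5p, 6 weeks against 1 week, at -0.084 with library totals alone, and the difference in miRNAs of at least 10 counts, 14 months against 6 weeks, at -17.8 after thinning to equal totals against 40.2. The number with at least 1 count also turned, from 62.2 to -65.4, without passing in either (adjusted p of 0.0595 and 0.119), and so did both numbers in the 3 comparisons of consecutive adult ages, none passing. Thinning removes the difference in depth itself. For miR-122-5p only the scaling differed between the settings. Mean TMM factors were 1.56 at 1 week and 0.986 at 6 weeks, and library totals alone moved the median of all miRNAs by -0.66. The value of -0.084 was not called as a fall (edgeR adjusted p = 0.165). The age fraction among the 20 adult libraries, 0.264, was 0.158 and no longer passed with log2 library total entered before age (0.248 to 0.293 without single libraries); age and total rise together there.

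For 6 months against 6 weeks (7 changed) library totals alone, library total as a covariate and leaving out mice 6 and 7 gave 3 each, limma-voom 15, and leaving out single libraries 1 to 9. For 12 months against 6 months (0 changed) no filter gave 3. For 14 months against 6 weeks (15 changed) no filter gave 24, limma-voom 52, the 2 ages alone 28, thinning 6, library total as a covariate 7, named miRNAs alone 9, and leaving out single libraries 8 to 22. Of 55 list tests 11 were called by camera. An estimated correlation gave 1, library totals alone 6, fry 16, and leaving out single libraries 7 to 16. The cause was not tested.

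Without single libraries the difference in total count ranged from -2615160 to -1416910 for 6 weeks against 1 week and from 1027420 to 1638890 for 14 months against 6 weeks. In miRNAs with at least 1 count it ranged from -199.4 to -155.9 and from 48.3 to 73.55, and with at least 10 counts from 30.6 to 49.1 for 14 months against 6 weeks. With 4 libraries against 5 the smallest exact p is larger, which bears on these calls. Depth limits what rare miRNAs can show: a floor of 3 counts is 4.90 CPM, scaled with TMM factors, in the shallowest library.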

Other observations

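All tests and miRNAs in this part were chosen only after their values were seen; the X-linked list itself was not.

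A cluster of the X chromosome named in no list, miR-322 and miR-503, which slow the cell cycle, was lower at 6 weeks than at 1 week: miR-322-5p fell by 3.13 ± 0.35 on the log2 scale, from 1125 ± 712 to 129 ± 35.2 CPM, with miR-542-3p at -3.27 ± 0.34, miR-503-5p at -2.96 ± 0.40 and miR-351-5p at -2.22 ± 0.35. All 4 were lower under the 3 other scalings too, between -2.24 and -3.92. Between 6 weeks and 14 months none of the 4 passed in edgeR (miR-322-5p -0.033 ± 0.33, adjusted p = 0.944; miR-351-5p -0.91 ± 0.36, adjusted p = 0.149).

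The rise of miR-741-3p from 6 weeks to 14 months may belong to a wider rise within its X-linked cluster. Of 32 other members in the table, 27 were summed because 5 repeat the counts of another member. Only miR-547-3p among them was abundant enough to test singly, and it did not pass from 6 weeks to 14 months. The sum thus cannot show that each member rose. The sum had 0.976 ± 1.09 CPM at 1 week (0.512 without mouse 27), 6.13 ± 2.86 at 6 weeks, 12.5 ± 5.73 at 6 months, 49.8 ± 31.7 at 12 months and 37.8 ± 13.0 at 14 months (n = 5 each). At 1 week no library had a count for more than 1 member. From 6 weeks to 14 months the exact permutation p was 0.00794 (adjusted p = 0.0198 over 5 tests), with 5 of 5 old libraries above every young one. The steps from 1 week to 6 weeks and from 6 weeks to 6 months each had an exact permutation p = 0.0159. That from 6 months to 12 months had an exact p = 0.00794 (adjusted p = 0.0198 for each of these steps). The step from 12 months to 14 months had an exact p = 0.595. These miRNAs are known from testis, and the labels state an equal share of both sexes without the sex of each mouse. If each age held both, sex alone would not set every old library above every young one; the labels do not state this by age, so sex stays open beside age. Handling that differed between ages stays open too.

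The ratio of 3p to 5p arms of miR-29a and miR-29c was higher at 14 months than at 6 weeks, without a separation from library depth for miR-29c. The log2 ratio of 3p to 5p went from 9.83 ± 0.41 to 11.02 ± 0.67 for miR-29a (exact permutation p = 0.0159, adjusted p = 0.0317; 4 of 5 above) and from 6.62 ± 0.69 to 8.07 ± 0.99 for miR-29c (p = 0.0397, adjusted p = 0.0397; 3 of 5 above). The 5p arms did not pass: miR-29a-5p 0.39 ± 0.45 (adjusted p = 0.617) and miR-29c-5p 0.035 ± 0.24 (adjusted p = 0.919), the latter at -0.21 with library totals alone, and miR-29b-2-5p 1.06 ± 0.71 (adjusted p = 0.383); no ratio was computed for miR-29b. With log2 library total in a linear model of the 25 libraries the difference was 1.04 ± 0.45 for miR-29a and 0.49 ± 0.47 for miR-29c. Counts of both 3p arms were nearly equal in every library, so the pair of ratios is not independent. Whether the 3p entries count the same reads is not stated, so neither ratio can be read as that of a single precursor.

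Unconservative entries, summed, took a larger share of shallow adult libraries. Within ages, log2 share fell as log2 total rose over the 20 adult libraries (slope -1.39, Pearson r = -0.887, permutation p = 3.0e-05; r = -0.844, p = 0.00021 in 18 libraries, without the pair farthest from the median total). The total is the denominator of the share, so a negative r is partly built in. The log2 count of these entries had a slope of -0.39 ± 0.19 on the log2 count of named miRNAs (95% interval -0.79 to 0.0044; permutation p = 0.0566), where growth in proportion gives 1 and a background of constant size gives 0. The interval lay below 0 without mouse 7, 13, 14, 15 or 18 (slopes of -0.43, -0.43, -0.46, -0.43 and -0.44). For the summed count growth in proportion is thus excluded, while a background of constant size stays open, since single libraries decide whether the interval holds 0. In mouse 6, where these entries held 0.368% of raw counts, unconservative_10_2277460 alone had 2173 CPM. It had 846 and 442 CPM in the shallow mice 7 and 16, and 12.4 and 38.2 in the deep mice 20 and 25. Mouse 12, of middle depth, had 905 CPM. The slope was not computed without this entry, so it cannot be assigned to the class as a whole. No biological explanation was tested.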
